A study of Homo sapiens with 14 samples.

How the data were processed

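The series holds 14 one-colour Agilent arrays of MCF-7 cells in 4 groups, siControl vehicle (n = 3), siControl E2 (n = 3), siFos vehicle (n = 4) and siFos E2 (n = 4). Per the labels' protocols, labelled cRNA was made from 100 ng of total RNA with a single dye, and the design text calls the arrays biological replicates. The labels give no dose of E2.

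The deposited scanner files hold intensity values per spot, the background-subtracted processed signal on a linear scale beside the median signal and the local background, per the file headers. The submitters' processing notes name Agilent Feature Extraction 10.10.1.1 and Partek 6.5 for all samples, whereas per the file headers the siFos arrays were read with Feature Extraction 10.10.1.1 and the siControl arrays with 10.7.3.1. The deposited table of the series holds intensity values that the authors had quantile normalized between arrays, as its values show: the median was 56.9 and the 75th percentile 705 in every column. It followed each array's processed signal with r between 0.9989 and 0.9999 on the log2 scale.

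Each array has 62976 spots, of which 58717 are not controls and stand for 42405 probes. Spots that the software marked as outliers, 351 to 490 per array, were left out, no spot was saturated, and the remaining spots of a probe were averaged. Genes were named through the probes' accessions in a RefSeq table of the assembly GRCh38.p14, used for names only; 24826 probes matched 19062 symbols, and 17579 kept the name in the files. The accession of 3283 probes differed between design versions, and the newer version was used. No coordinates are given, since the files use another build.

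The processed signal was taken to log2 and each array's 75th percentile over non-control probes was subtracted. Probes well above background on every array of at least 1 group were kept (27222), and each gene was represented by its probe with the highest mean signal, which left 22630 genes, 14252 of them with a symbol. Limma 3.58.1 in R 4.3.3 fitted the 4 group means on all 14 arrays, with no block, and its moderated test (two-sided, prior degrees of freedom 1.72) was adjusted by Benjamini and Hochberg within each of 5 comparisons: E2 in siControl cells, E2 in siFos cells, the FOS siRNA in vehicle, the FOS siRNA in E2, and their interaction. Genes were called at adjusted p under 0.05. Errors of fold changes are limma's standard errors. On simulated data with 100 genes changed by each of 2 sizes among 22630, the test recovered 66% of genes changed by 0.5 (log2) and 87% of those changed by 1 for E2 in siControl cells, 74% and 92% for the siRNA in vehicle, 68% and 95% for the siRNA in E2, 72% and 90% for E2 in siFos cells, and 58% and 75% for the interaction, with 5, 13, 5, 3 and 2 false calls. Far fewer genes changed there than were called in the data (14.2% to 60.3%), so neither the recovery nor the false calls carry over. The adjustment allows on average a share of up to 0.05 of the called genes to be false.

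Gene lists of 21 kinds were fixed beforehand: estrogen-induced and estrogen-repressed genes, AP-1 subunits, AP-1 target genes, immediate early genes, G1/S and DNA replication, G2/M and mitosis, homologous recombination, CDK inhibitors and the RB family, p53 targets, the BCL2 family, interferon response, unfolded protein and ATF4 response, cholesterol and fatty acid synthesis, luminal markers, basal and mesenchymal markers, steroid receptors and coregulators, growth factor receptors and ligands, ribosome biogenesis, hypoxia response, and markers of fibroblasts, endothelium and leukocytes. UBE2C, IFI27, PHB2 and LYZ were not on the array by name. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with missing values replaced by the group mean, and again with an estimated correlation. Members were counted over all genes tested and adjusted over the list alone.

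The genes named are, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall among gene symbols whose groups of arrays did not overlap (without that condition for the interaction; clone, locus and open reading frame names were passed over), up to 3 called members of each list with the largest change (where none was called, up to 2 members with the smallest p), and FOS. A gene named in 1 comparison could be given in the others. Overlaps between comparisons are set beside the number for independent lists, and where arrays are shared also beside 20 simulations of unchanged groups. For genes chosen in siControl cells, slopes between arms are of the siFos on the siControl E2 effect, through the origin. For genes chosen in siFos cells the inverse of the reverse slope is given. Both have 95% intervals from 1000 bootstrap samples of genes.

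The alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, the authors' table, no filter and a stricter filter, every probe, a replicate block, array weights, a trended and robust eBayes, fits of only the compared groups, and leaving out each array. The mean signal column named for normexp is absent from the files, so the median signal was used. A block for the slide was not run, since slide and siRNA coincide for the siRNA effects and the E2 effects and interaction lie within slides. Changes of at least 2-fold and limma's treat test against 1.5-fold were added after the data were seen, as were lists of motile cilium, antigen presentation, and apolipoprotein and cholesterol efflux genes, which the closing section alone uses. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.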

Results

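Gene expression was measured in MCF-7, an estrogen receptor-positive human breast cancer cell line, after transfection with a control siRNA (siControl) or with a pool of siRNAs against FOS (siFos). FOS is a subunit of AP-1, a transcription factor built from FOS and JUN family proteins, and the study's title asks how AP-1 and the estrogen receptor act together on gene expression and proliferation. The medium was changed 6 h after transfection to phenol red-free medium with 2% charcoal-treated serum, which is poor in estrogens, and 72 h later the cells received vehicle or estradiol (E2) for 24 h. The 14 one-colour arrays comprised 3 of siControl vehicle, 3 of siControl E2, 4 of siFos vehicle and 4 of siFos E2 cells. The 75th percentile of the processed signal lay between 569 and 856 units per array, and between 59.6% and 65.6% of the probes were well above background. Signals of the same group correlated across probes with r between 0.995 and 0.997, and the median SD of a gene within a group was 0.07 to 0.09 on the log2 scale. The number of arrays limits the precision of every value below.

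The siFos arrays all lay on 1 slide and the siControl arrays all on the other, with a different scan and a different version of the image software for each slide. Every difference between siFos and siControl cells is therefore also a difference between slides, scans and software versions, and these cannot be told apart, since no slide held both siRNAs. Each E2 effect was measured within a slide, although vehicle arrays filled row 1 and E2 arrays row 2 of both slides. Between these rows the 7 spike-in probes well above background differed by -0.181 to -0.115 (log2, E2 minus vehicle), with an SD of 0.0228, against an SD of 0.379 over genes. The first component of a principal component analysis held 56.9% of the variance and separated all 4 groups. The p-values below measure the spread between these samples, and the comparisons, gene lists and rule for naming genes were fixed before the data were examined.

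FOS, the targeted gene, was lower in siFos cells and higher with E2. Its signal relative to the 75th percentile of the array lay between -2.66 and -2.58 (log2) on the 4 siFos vehicle arrays and between -1.27 and -1.04 on the 3 siControl vehicle arrays. With E2 it lay between -1.27 and -1.13 on the 4 siFos arrays and between -0.17 and 0.01 on the 3 siControl arrays. FOS was thus 2.77-fold lower with the FOS siRNA in vehicle (SE 0.06 on the log2 scale, adjusted p = 1.71e-09, limma) and 2.12-fold lower in E2 (SE 0.06, adjusted p = 1.38e-08). E2 raised FOS 2.05-fold in siControl cells and 2.68-fold in siFos cells, a difference of 0.39 ± 0.08 (log2, adjusted p = 0.0104) that was lost with median centring (0.35) and normexp (0.22), the adjusted p ranging from 0.00354 to 0.0728 over the alternatives. In signal, siFos cells with E2 held about as much FOS signal as siControl cells without it. The direction matched the labels on all 14 arrays, although 1 probe measured FOS and the slide difference applies to it as to other genes.

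**Figure D1:**
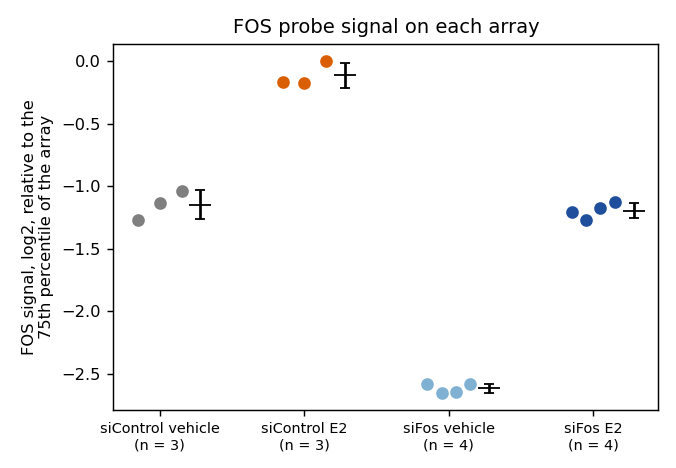
FOS signal of each of the 14 arrays, as log2 of the processed signal relative to the array's 75th percentile; points are arrays, and the bar beside each group is its mean with 1 SD. The 4 siFos vehicle arrays lie between -2.66 and -2.58, below all other arrays.

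The comparison of E2 with vehicle in siControl cells asked which transcripts 24 h of estradiol changed without knockdown. Estradiol strongly raised genes with a known estrogen response. PDZK1, which encodes a scaffold for membrane transporters, was 27.3-fold higher (log2 4.77 ± 0.10, SE, n = 3 per group), EGR3, an immediate early transcription factor, was 16.9-fold higher (4.08 ± 0.10) and PGR, the progesterone receptor gene, was 9.49-fold higher (3.25 ± 0.08). AREG, a ligand of the EGF receptor, rose 6.90-fold, UGT2B15, whose enzyme glucuronidates steroids, rose 18.8-fold, and MYC rose 2.34-fold. Among the genes that fell most were PSCA, a cell surface antigen gene (7.72-fold lower, SE 0.05), and DAB2, an endocytic adaptor gene (7.79-fold lower, SE 0.06). BMF and BIK, which encode pro-apoptotic proteins of the BCL2 family, fell less far (4.32-fold and 3.05-fold lower). The other BMF probe gave a log2 change of -1.38.

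Of 39 measured estrogen-induced genes, 38 rose with E2 in siControl cells and 1 did not pass (median log2 1.32), and all 15 estrogen-repressed genes fell (median -1.43), among them IL1R1 at -2.29. All 43 genes of the G1/S and DNA replication list rose, with a median of 0.84, as did all 38 genes of the G2/M and mitosis list, with a median of 0.71. GINS4, a subunit of the replicative helicase, rose by 1.24, RRM2, which makes deoxynucleotides, by 1.22, and AURKB, a mitotic kinase, by 0.91. Of 22 genes of homologous recombination 21 rose, including EXO1 by 1.17, and of 22 ribosome biogenesis genes 20 rose, including NOP56 by 0.84. Of 21 genes of cholesterol and fatty acid synthesis 17 rose and 4 did not pass (median 0.50), with STARD4, a cholesterol transporter, up by 1.25 and DHCR7, the last enzyme of cholesterol synthesis, by 0.80. Camera, limma's test of a list against the other genes, called these 7 lists with its preset correlation and also with an estimated correlation.

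Interferon response genes went down with E2 in siControl cells, 24 of 28 falling and 2 rising (median -0.75), among them RSAD2 at -1.75 and IFI44L at -1.62; camera called this list, but with adjusted p = 0.369 with an estimated correlation. Of 21 p53 target genes 15 fell and 2 rose, with TP53INP1 at -1.54 and BTG2, an anti-proliferative gene, at -1.17 (adjusted p = 0.0588 with an estimated correlation). Of 20 unfolded protein and ATF4 response genes 11 rose and 3 fell (adjusted p = 0.369 with an estimated correlation), and quantile normalization also ended this call, at adjusted p = 0.0759, the adjusted p ranging from 0.0514 to 0.369 over the alternatives. Camera did not call the other lists: AP-1 subunits (3 rose and 7 fell of 15), AP-1 target genes (7 and 6 of 18), immediate early genes (7 and 9 of 18), CDK inhibitors and the RB family (4 and 4 of 10), the BCL2 family (6 and 8 of 16), luminal epithelial markers (3 and 8 of 18), basal and mesenchymal markers (4 and 5 of 15), steroid receptors and coregulators (4 and 4 of 17), growth factor receptors and ligands (11 and 12 of 26) and the hypoxia response (6 and 4 of 16). In these, single genes still moved far, such as CCN2, a matricellular growth factor gene, at -2.55, CDKN2B, a CDK inhibitor gene, at -1.47, ELF3, an epithelial transcription factor gene, at -1.38, and SNAI2, a regulator of epithelial plasticity, at -1.92. The median, mean and camera direction of the AP-1 target, CDK inhibitor and growth factor lists differed in sign. Adjusted over the list alone, every count in this comparison was the same except that 9 luminal markers fell.

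In all, 10606 of 22630 genes passed (46.9%), 5319 higher and 5287 lower with E2, by limma with Benjamini-Hochberg adjustment; 419 rose and 584 fell at least 2-fold, but 204 and 180 in the normexp alternative, which changes the signal column, the background correction, the offset and the normalization together. ARHGAP36, a regulator of hedgehog signalling, and UGT2B11 were not well above background on any vehicle array, and were at least 16.8-fold and at least 15.2-fold higher with E2. In such bounds each dim array takes the larger of its own signal and the lowest signal called well above background on it, so the bounds hold for the processed signal only. With normexp the log2 changes were smaller, at 1.98 for ARHGAP36, 1.53 for UGT2B11, -1.23 for CCN2, -1.03 for SNAI2, -0.83 for CDKN2B, -0.90 for IFI44L and -0.67 for RSAD2.

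The comparison of siFos with siControl cells in vehicle asked what the FOS siRNA changed without estradiol. Genes of DNA replication and repair were lower in siFos cells. MCM10, a factor that starts DNA replication, was 3.50-fold lower (log2 -1.81 ± 0.06, SE, n = 4 and 3), RAD51, the recombinase of homologous repair, 3.17-fold lower (-1.66 ± 0.05) and E2F2, a transcription factor of the G1/S switch, 3.39-fold lower (-1.76 ± 0.05). CACNG6, a calcium channel subunit gene, was 9.53-fold higher (3.25 ± 0.06) and LTB, a TNF family cytokine gene, 9.92-fold higher (3.31 ± 0.27). ESR1, the gene of the estrogen receptor, was 1.99-fold lower on its brightest probe (log2 SE 0.06); its 3 probes all fell, the smallest change being -0.25.

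All 43 G1/S and DNA replication genes fell with the FOS siRNA in vehicle (median -1.09; adjusted p = 0.0688 with an estimated correlation), and all 38 G2/M and mitosis genes fell (median -1.0; adjusted p = 0.0688 with an estimated correlation), with KIF2C, a mitotic kinesin gene, at -1.25. ORC1, a subunit of the origin recognition complex in the G1/S list, fell by 1.61. Of 22 homologous recombination genes 21 fell, BLM at -1.46 and EXO1 at -1.60 (adjusted p = 0.0688 with an estimated correlation). Of 22 ribosome biogenesis genes 18 fell (median -0.31; adjusted p = 0.0706 with an estimated correlation). Of 39 estrogen-induced genes 24 fell and 7 rose, with MYB at -1.38, GREB1, a cofactor of the estrogen receptor, at -1.05 and CCN5 at -1.77 (adjusted p = 0.341 with an estimated correlation). The other GREB1 probe gave -0.46. Of 15 estrogen-repressed genes 11 rose and 2 fell, with PSCA at 1.25 (adjusted p = 0.0688 with an estimated correlation).

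Other members of AP-1 were higher in siFos vehicle cells: 12 of 15 AP-1 subunits rose and 3, FOS among them, fell, with JDP2 at 1.15 and ATF3 at 0.82 (adjusted p = 0.0688 with an estimated correlation). The 4 ATF3 probes ranged from -0.1 to 0.82, with 3 called higher. AP-1 target genes went up as well, 13 of 18 rising and 2 falling, with LAMC2, a laminin chain gene, at 1.40, PLAUR, the urokinase receptor gene, at 0.99 and MMP9, a matrix protease gene, at 0.88 (adjusted p = 0.0688 with an estimated correlation). Of 18 immediate early genes 15 rose and 1 fell, with KLF2 at 1.42 and EGR1 at 0.92 (adjusted p = 0.0688 with an estimated correlation). Of 28 interferon response genes 15 rose and none fell, with IFIT2 at 1.61 and OASL at 1.34 (adjusted p = 0.484 with an estimated correlation). Of 21 p53 target genes 15 rose and 3 fell (adjusted p = 0.0688 with an estimated correlation), and of 16 BCL2 family genes 10 rose and 2 fell, BCL2 itself at -0.92 (adjusted p = 0.0708 with an estimated correlation). Of 26 growth factor receptors and ligands 17 rose and 6 fell (adjusted p = 0.0688 with an estimated correlation); the 3 EGFR probes disagreed, 2 higher and 1 lower, between -1.09 and 1.13.

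Camera did not call the remaining lists in vehicle, with 10 rising and 6 falling of 20 unfolded protein and ATF4 genes, 9 and 4 of 21 cholesterol genes, 8 and 3 of 15 basal markers, 7 and 6 of 18 luminal markers, 8 and 3 of 17 steroid receptors and coregulators, 4 and 7 of 16 hypoxia genes, and 4 and 4 of 10 CDK inhibitors and RB genes. For CDK inhibitors, hypoxia genes and non-epithelial markers the median, mean and camera direction differed in sign. Adjusted over the list alone, the counts differed for 1 list, with 7 unfolded protein genes falling. Markers of fibroblasts, endothelium and leukocytes, which an epithelial line should lack, had 11 of 20 members above the filter, and camera called them in no comparison; 4 rose and 4 fell with E2 in siControl cells, 4 rose and 2 fell with the siRNA in vehicle, 4 rose and 1 fell with it in E2, and 3 rose and 5 fell with E2 in siFos cells. Adjusted over the list alone these counts were the same.

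In all, 13512 genes (59.7%) differed between siFos and siControl cells in vehicle, 6772 higher and 6740 lower, of which 682 and 689 by at least 2-fold (209 and 215 with normexp). With median centring the higher share was 41% instead of 50.1% and the 2-fold counts 588 and 838, so the even balance depends on the scaling. PSAPL1, DSCAML1, SH3PXD2A, APOD, an apolipoprotein gene, and DNAAF1, a factor that assembles ciliary dynein arms, were not well above background on any siControl vehicle array and were at least 11.4-fold, 6.66-fold, 7.97-fold, 5.76-fold and 2.99-fold higher in siFos cells. CGA, the common subunit of the glycoprotein hormones, fell by 2.35 and SHCBP1 fell by 2.14, while BMP5, a bone morphogenetic protein gene, was at least 2.46-fold lower. With normexp the log2 changes were 1.80 for LTB, 1.24 for PSAPL1, 0.80 for DSCAML1, 0.99 for SH3PXD2A, 0.72 for APOD, 0.44 for DNAAF1, -0.44 for BMP5, 0.59 for PLAUR and 0.43 for EGFR.

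**Figure D2:**
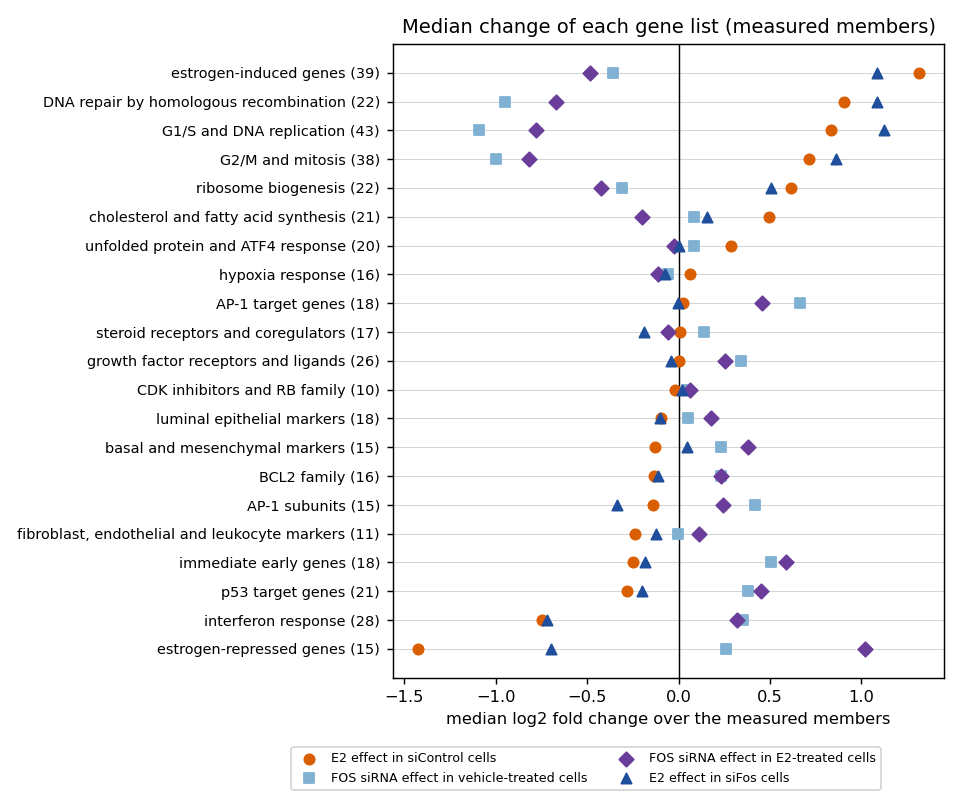
Median log2 fold change of each gene list fixed beforehand, over its measured members (number in brackets), for the 4 pairwise comparisons. The G1/S list lies at 0.84 and 1.13 for E2 in siControl and siFos cells and at -1.09 and -0.78 for the FOS siRNA in vehicle and in E2.

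The comparison of siFos with siControl cells in E2 asked what the FOS siRNA changed in the presence of estradiol. Several genes that estradiol represses were higher in siFos cells. PSCA was 5.6-fold higher (log2 2.48 ± 0.05, SE, n = 4 and 3), BLNK, a signalling adaptor gene, 2.97-fold higher (1.57 ± 0.04) and BIK 2.88-fold higher (1.52 ± 0.03). CACNG6 stood 32.8-fold higher (5.04 ± 0.06) and KPNA7, an importin gene, 9.54-fold higher (3.25 ± 0.07). GREB1 was 2.62-fold lower (-1.39 ± 0.10), PGR 2.34-fold lower (-1.23 ± 0.08) and SLC7A5, an amino acid transporter gene, 2.55-fold lower (-1.35 ± 0.06). The other GREB1 probe gave -0.89.

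Of 15 estrogen-repressed genes 14 rose with the FOS siRNA in E2 (median 1.02), a call that held with an estimated correlation (adjusted p = 0.0304). Of 39 estrogen-induced genes 29 fell and 1 rose (median -0.48; adjusted p = 0.0903 with an estimated correlation). The 43 G1/S genes all fell (median -0.78; adjusted p = 0.0609 with an estimated correlation), MCM10 at -1.29, and so did the 38 G2/M genes (median -0.82; adjusted p = 0.0609 with an estimated correlation), with PTTG1, the securin gene, at -1.01. Of 22 homologous recombination genes 21 fell, RAD51 at -1.30 (adjusted p = 0.0642 with an estimated correlation), and of 22 ribosome biogenesis genes 19 fell (adjusted p = 0.0609 with an estimated correlation). Of 21 cholesterol genes 14 fell and 2 rose, with HMGCS1, a mevalonate pathway enzyme gene, at -0.80 (adjusted p = 0.117 with an estimated correlation); quantile normalization also ended this call, at adjusted p = 0.0569.

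Of 18 AP-1 target genes 15 rose and 1 fell with the FOS siRNA in E2, MMP9 at 1.32 and PLAU, the urokinase gene, at 1.24 (adjusted p = 0.0609 with an estimated correlation). AP-1 subunits rose in 9 and fell in 3 of 15 cases, with JDP2 at 1.42 and FOSB at 0.92 (adjusted p = 0.144 with an estimated correlation). Of 18 immediate early genes 13 rose and 2 fell, CCN2 at 1.95 (adjusted p = 0.0903 with an estimated correlation). Basal and mesenchymal markers rose in 10 of 15 cases and none fell, SNAI2 at 1.90 (adjusted p = 0.0609 with an estimated correlation). Of 28 interferon genes 17 rose and none fell, IFIT2 at 1.95 (adjusted p = 0.575 with an estimated correlation). Of 21 p53 target genes 15 rose and 3 fell, GDF15 at 1.15 (adjusted p = 0.0609 with an estimated correlation), and of 16 BCL2 family genes 9 rose and 2 fell (adjusted p = 0.132 with an estimated correlation). Of 26 growth factor receptors and ligands 16 rose and 4 fell, TGFB2 at 1.47 (adjusted p = 0.0609 with an estimated correlation). The lists that camera did not call were luminal markers (10 rose and 6 fell), steroid receptors (5 and 4), unfolded protein genes (8 and 8), hypoxia genes (4 and 6) and CDK inhibitors (5 and 3). Adjusted over the list alone, 2 estrogen-induced genes and 11 basal markers rose and 2 AP-1 targets and 15 cholesterol genes fell, with the other counts the same.

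In all, 13642 genes (60.3%) differed between siFos and siControl cells in E2, 6982 higher (51.2%) and 6660 lower; with median centring the higher share was 38.7%, so the balance of directions depends on the scaling. At least 2-fold changes numbered 989 upward and 468 downward (361 and 164 with normexp). LTB and DNAI7, a ciliary dynein subunit gene, were not well above background on any siControl E2 array and were at least 13.9-fold and at least 6.42-fold higher. MGP, an inhibitor of calcification, fell by 1.88 and S100A7 fell by 2.17, while TUBA3FP, a tubulin pseudogene at -3.34 (adjusted p = 0.0215), lost its call without siFos E2 replicate 1 (-2.87, adjusted p = 0.0581) and when only both E2 groups were fitted (adjusted p = 0.0908). Its log2 change ranged from -4.39 to -1.43, the smallest without siControl E2 replicate 3, and its adjusted p from 0.0068 to 0.0908 over the alternatives, by limma. The SD between the 3 siControl E2 arrays was 3.32. With normexp the log2 changes were -1.75 for TUBA3FP, 1.43 for LTB, 0.78 for DNAI7, 0.80 for CCN2, 0.98 for SNAI2, 0.92 for TGFB2, 0.42 for FOSB and -1.25 for S100A7. The siRNA effects in vehicle and in E2 correlated across genes at r = 0.82, although genes are not independent replicates. In both, 5293 genes were higher and 5008 lower, against 2089.4 and 1983.6 for independent lists. Both effects set the siFos slide against the siControl slide. A difference between slides, scans or software versions would therefore raise this agreement too, and it cannot be told apart from the siRNA.

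The comparison of E2 with vehicle in siFos cells asked which responses to estradiol remained after knockdown. The classical estrogen targets still rose strongly. PDZK1 was 16.6-fold higher (log2 4.05 ± 0.09, SE, n = 4 per group), GREB1 9.90-fold (3.31 ± 0.09), MYBL1, a transcription factor gene of the MYB family, 9.12-fold (3.19 ± 0.06), PGR 6.82-fold (2.77 ± 0.07) and AREG 5.6-fold (2.48 ± 0.07). The replication genes MCM10 and CDC45 were 3.32-fold higher (1.73 ± 0.06) and 3.03-fold higher (1.60 ± 0.06). PSCA was 3.29-fold lower (-1.72 ± 0.04) and IL1R1 2.59-fold lower (-1.37 ± 0.11).

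All 39 estrogen-induced genes rose with E2 in siFos cells (median 1.08), and 14 of 15 estrogen-repressed genes fell (median -0.70). All 43 G1/S genes rose (median 1.13), all 38 G2/M genes rose (median 0.86), CDCA3 by 1.24, and 21 of 22 homologous recombination genes rose, RAD54L by 1.53. Of 22 ribosome biogenesis genes 21 rose (median 0.51). Camera called these 6 lists with an estimated correlation too. Interferon genes fell in 25 of 28 cases and rose in 1, IFI44L at -1.61 (adjusted p = 0.242 with an estimated correlation). Of 21 p53 target genes 14 fell and 1 rose, TP53INP1 at -0.87 (adjusted p = 0.0588 with an estimated correlation), and of 15 AP-1 subunits 9 fell and 2 rose (adjusted p = 0.113 with an estimated correlation). Of 21 cholesterol genes 10 rose and 2 fell (median 0.16; adjusted p = 0.259 with an estimated correlation), and quantile normalization also ended this call, at adjusted p = 0.0706.

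Camera did not call AP-1 target genes in siFos cells (6 rose and 6 fell with E2), immediate early genes (5 and 10), CDK inhibitors (2 and 3), the BCL2 family (5 and 8), unfolded protein genes (9 and 6), luminal markers (6 and 9), basal markers (5 and 3), steroid receptors (2 and 9), growth factor genes (10 and 12) or hypoxia genes (4 and 7). For AP-1 targets, CDK inhibitors, steroid receptors and unfolded protein genes the median, mean and camera direction did not all share a sign. Adjusted over the list alone, 22 homologous recombination genes, 2 interferon genes and 11 growth factor genes rose, 15 p53 targets fell, and the other counts were the same. In all, 11515 genes (50.9%) passed, 5553 higher and 5962 lower, of which 432 and 182 by at least 2-fold (194 and 39 with normexp). BMPER, a BMP-binding protein gene, was not well above background on any siFos vehicle array and was at least 18.8-fold higher with E2, and ADAMTS18, a secreted protease gene, was at least 4.98-fold lower. With normexp the log2 changes were 2.01 for BMPER, -0.73 for ADAMTS18 and -0.81 for IFI44L.

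The interaction asked whether the E2 effect differed between siFos and siControl cells, and several estrogen-repressed genes fell less in siFos cells. BLNK fell by 2.04 with E2 in siControl cells and by 0.72 in siFos cells, a difference of 1.32 ± 0.06 (SE, n = 4, 4, 3 and 3). For PSCA the difference was 1.23 ± 0.07, for BMF 1.08 ± 0.07 and for BIK 0.91 ± 0.05. TFF1, a secreted trefoil peptide gene induced by estrogen, rose by 0.62 in siControl cells and by 1.60 in siFos cells (difference 0.98 ± 0.05). It was lower in siFos than in siControl cells in vehicle (-1.01) and differed by -0.03 in E2. PRSS23, a serine protease gene, rose by 2.62 in siControl cells and by 0.89 in siFos cells (difference -1.73 ± 0.07).

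Of 15 estrogen-repressed genes 12 had a weaker fall in siFos cells and none a stronger one (median interaction 0.68), and the call held with an estimated correlation (adjusted p = 0.00244). Of 21 cholesterol and fatty acid genes 18 had a lower E2 effect in siFos cells and none a higher one (median -0.34), which also held (adjusted p = 0.00433 with an estimated correlation). STARD4 rose by 1.25 with E2 in siControl cells and had a log2 change of 0.21 in siFos cells (difference -1.04 ± 0.16), and SQLE, the squalene epoxidase gene, had a difference of -0.53 ± 0.07 and FDFT1, the squalene synthase gene, of -0.49 ± 0.05. The E2 effect was higher in siFos cells for 26 of 43 G1/S genes and lower for none, E2F2 by 0.67 and TK1, thymidine kinase, by 0.61 (adjusted p = 0.166 with an estimated correlation). It was higher for 16 of 38 G2/M genes and lower for none, CENPM by 0.41 (adjusted p = 0.194 with an estimated correlation), and higher for 11 of 22 homologous recombination genes and lower for none (adjusted p = 0.194 with an estimated correlation).

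Of 39 estrogen-induced genes 18 had a lower E2 effect in siFos cells and 5 a higher one, EGR3 and HEY2 each at -0.96 and PGR at -0.48 (adjusted p = 0.194 with an estimated correlation). Steroid receptors and coregulators had 8 lower of 17 (adjusted p = 0.166 with an estimated correlation), ribosome biogenesis 6 lower of 22 (adjusted p = 0.177 with an estimated correlation), the hypoxia response 7 lower and 1 higher of 16 (adjusted p = 0.312 with an estimated correlation), the unfolded protein and ATF4 response 3 lower of 20 (adjusted p = 0.194 with an estimated correlation) and p53 target genes 4 higher and 2 lower of 21 (adjusted p = 0.220 with an estimated correlation). Camera did not call AP-1 subunits (3 higher and 1 lower), AP-1 targets (3 and 3), immediate early genes (2 and 3), interferon genes (1 and 3), CDK inhibitors (3 and 1), the BCL2 family (5 and 4), luminal markers (6 and 1), basal markers (4 and 1), growth factor genes (9 and 3) or non-epithelial markers (2 and 1). For immediate early, BCL2 family and interferon genes the median, mean and camera direction differed in sign. Adjusted over the list alone, the higher and lower counts were 13 and 0 for estrogen-repressed, 18 lower for cholesterol, 36 and 0 for G1/S, 20 and 0 for G2/M, 11 and 1 for homologous recombination, 5 and 21 for estrogen-induced genes, 0 and 7 for unfolded protein genes, 0 and 10 for ribosome biogenesis, 7 and 2 for p53 targets and 1 and 8 for steroid receptors. They were 3 and 2 for AP-1 subunits, 5 and 4 for AP-1 targets, 3 and 3 for immediate early genes, 4 and 2 for CDK inhibitors, 6 and 5 for the BCL2 family, 7 and 1 for luminal markers, 10 and 6 for growth factor genes and 2 and 2 for non-epithelial markers, and unchanged for the other lists.

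In all, 3212 genes (14.2%) had an interaction, 1662 higher and 1550 lower, of which 101 and 45 by at least 2-fold (13 and 7 with normexp). The higher share was 51.7%, and 59.2% with quantile normalization and 58.5% in the authors' value table. The count depended on the processing, at 1542 with median centring and 1999 without the filter on dim probes. Among genes well above background on every array, CACNG6 had an interaction of 1.78 ± 0.08 and SERHL2 of 1.59 ± 0.07, while TMEM229A (3.6), GSTA5 (2.36) and KCND2 (-2.15) rested on groups at background. ERG (2.61 ± 0.68) lost its call in the authors' value table (0.93), with normexp (0.54), without the filter and without siControl vehicle replicate 3 (2.27), its adjusted p ranging from 0.0107 to 0.563 over the alternatives. With normexp the interactions were 0.75 for CACNG6, 0.76 for PSCA, 0.62 for TFF1, -0.52 for HEY2, 0.55 for TMEM229A, 0.28 for GSTA5 and -0.42 for KCND2. Each arm of the interaction lay on its own slide, so a difference between arms is also a difference between slides.

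**Figure D3:**
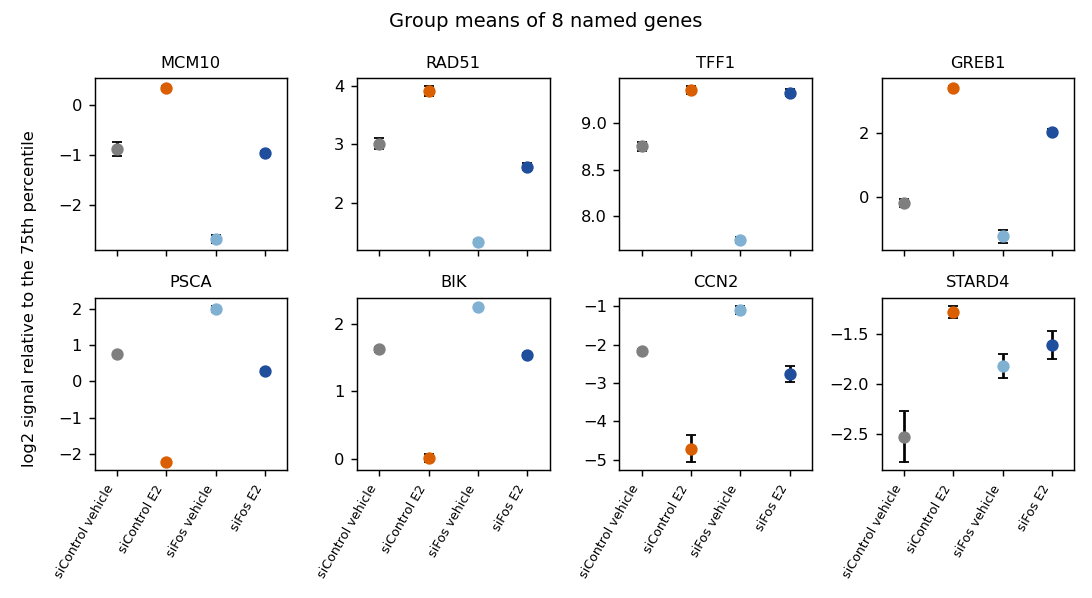
Group means of 8 genes in the 4 groups, as log2 signal relative to the array's 75th percentile, with bars of 1 SD (n = 3 for siControl and 4 for siFos groups). The estrogen-repressed PSCA and BIK fall with E2 less far in siFos than in siControl cells, while STARD4 rises with E2 by 1.25 in siControl cells.

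Across all genes, the E2 effects in siFos and siControl cells correlated at r = 0.762. These effects share no arrays. In both arms 3760 genes rose and 4147 fell, against 1305.2 and 1392.9 for independent lists, and 40 and 114 went opposite ways. Among the 584 genes that E2 lowered at least 2-fold in siControl cells the median was -1.29 there and -0.74 in siFos cells, with a slope of 0.53 (95% bootstrap interval over genes 0.51 to 0.55). Among the 419 genes that it raised at least 2-fold the medians were 1.42 and 1.22, with a slope of 0.78 (0.75 to 0.82). For genes chosen in siFos cells the inverse of the slope of the siControl on the siFos effect was 0.86 (0.80 to 0.93) for the 182 lowered and 1.06 (1.02 to 1.11) for the 432 raised. Choosing genes in an arm inflates its effect, which lowers the first slopes and raises the second. Neither choice alone gives the size of the remaining effect. IL1R1 and BMF are among the lowered genes and PDZK1 and PGR among the raised ones.

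**Figure D4:**
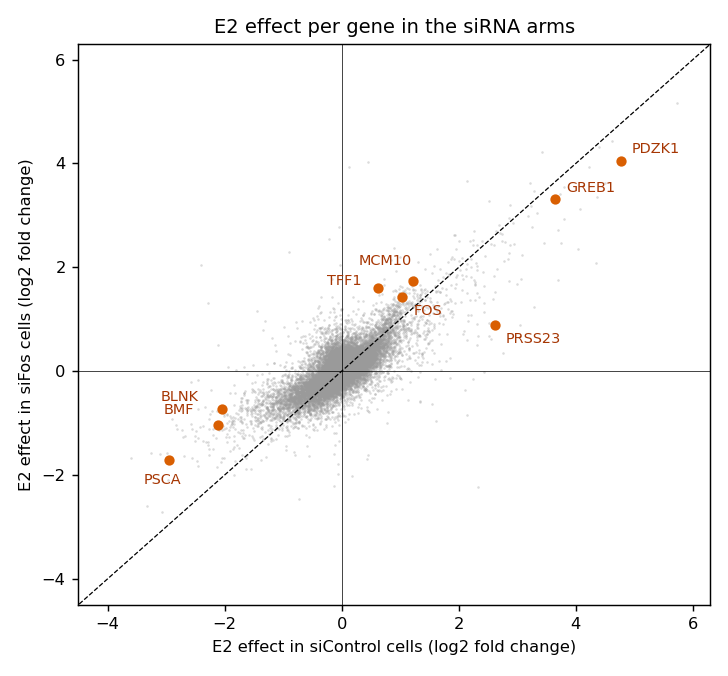
E2 effect (log2 fold change) of each of the 22630 genes in siControl cells (horizontal) and siFos cells (vertical); the dashed line marks equal effects. PSCA, BMF and BLNK lie above the line, having fallen less in siFos cells, and PRSS23 lies below it.

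The genes that estradiol changed in siControl cells mostly differed the other way with the FOS siRNA in E2. Of the genes that E2 raised, such as GREB1 and RAD51, 3714 were lower with the siRNA and 521 higher; of those that it lowered, such as PSCA and BIK, 3755 were higher and 439 lower. Independent lists would give 1565.4, 1641.1, 1631.2 and 1556 genes. These comparisons share the siControl E2 arrays with opposite sign, so their correlation across genes of -0.58 stands beside -0.53 in simulated unchanged groups, with covariances of -0.155 observed and -0.012 simulated, and 0 genes called in both in the simulation. Part of the excess may come from the shared arrays, which were too few to split. For the FOS siRNA effect in vehicle, which shares the siControl vehicle arrays with the same sign, the correlation was -0.28 against 0.54 simulated (covariance -0.0697 against 0.0122), with 3055 and 2800 genes opposite and 1089 and 760 the same.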

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

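The tests of the difference in E2 effect between arms and of other splits of the arrays were planned, as was the spike-in test; the tests of signal scale, signal floor and E2 exposure, and the count of slides holding both siRNAs, were chosen only after the results were seen.

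Genes that E2 lowered in siControl cells fell less in siFos cells. The slope was 0.53 (0.51 to 0.55) over the 584 genes lowered at least 2-fold in siControl cells and 0.858 over the 182 chosen in siFos cells. Choosing genes in an arm pulls these values apart. A signal scale compressed alike at every level on the siFos slide would shrink rises alike, but raised genes had a slope of 0.782 (0.746 to 0.815). Genes chosen in siFos cells differed the same way (0.858, 0.80 to 0.933, against 1.063, 1.023 to 1.107). These intervals resample genes and leave out the spread between arrays, and a compression that varies with signal level was not tested. A signal floor or background subtraction is argued against by normexp, with slopes of 0.586 (0.56 to 0.613) and 0.775 (0.739 to 0.808), and by genes well above background on all 14 arrays (0.555 and 0.813). Weaker E2 exposure of the siFos cells stays open: 26 of 43 G1/S genes rose more in siFos cells and none less, but that list's call is lost with an estimated correlation (adjusted p = 0.166), and 18 of 39 estrogen-induced and 18 of 21 cholesterol genes had a lower E2 effect. The knockdown itself, and a difference in culture between the arms, stay open as well, untested, as each arm lay on its own slide.

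The difference between siFos and siControl arrays was wide, with 13512 genes called in vehicle and 13642 in E2. Over 7 of 10 spike-in probes, which follow labelling, hybridization, scan and software but not the cells, the SD of the siFos minus siControl difference was 0.155, against 0.457 over genes, a ratio of 0.34. All 7 were higher on the siFos arrays, by a median of 0.409 (0.246 to 0.688) after each array's 75th percentile over non-control probes was subtracted. That percentile was lower on the siFos arrays (569 to 651 units) than on the siControl arrays (710 to 856). The shift therefore also carries the level of gene signal and is not a measure of the slides alone. The SD leaves it out. It was as large as the median change of a called gene in vehicle (0.409), and it leaves the higher and lower counts dependent on the scaling. The ratio lay between the bounds set beforehand, so that a technical share cannot be told apart from the siRNA; the same ratio for E2 minus vehicle was 0.0601, with all 7 lower in E2 (median -0.159). A difference in culture, transfection or RNA batch cannot be told apart from the siRNA either, as 0 slides held both siRNAs. The knockdown stays open as a biological explanation, untested apart from these. With a single pool of siRNAs against FOS, it cannot be told apart from other effects of that pool either.

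Only the real split of the arrays gave as many called genes for the FOS siRNA in vehicle (1 of 35 splits; 13512 genes, highest other 8158) and in E2 (1 of 35; 13642, highest other 8410), both under the 1 in 20 set beforehand, which argues against chance, but the real split follows the slide. The same holds for E2 in siFos cells, within 1 slide (1 of 35 splits; 11515 genes, highest other 2). For E2 in siControl cells the 10 splits are too few for a share under 0.05 (1 of 10; 10606 genes, highest other 1). For the interaction 3 of 100 splits, the real one included, gave as many genes (3212, highest other 3686), which is also under 1 in 20. This share cannot decide about chance, since the splits mixed the siRNA labels within each treatment. The wide difference between siRNAs and slides then enters the spread between arrays (median of the other splits 0 genes) or the interaction itself. The 2 other splits with as many genes, 3686 and 3430, kept the siRNA label of all 7 E2 arrays and of 3 of the 7 vehicle arrays, and so put that difference into the interaction.

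The E2 effect differed between the arms, by the tested interaction, for 42 of the 53 genes whose E2 effect is given. Some of these genes were named because their interaction was called, so this share does not measure how common a difference was. Over all genes tested, 14.2% had an interaction. Estrogen-repressed and other lowered genes fell less in siFos cells: CACNG6 (1.78), SERHL2 (1.59), BLNK (1.32), DAB2 (1.24), PSCA (1.23), BMF (1.08), IL1R1 (0.92), BIK (0.91), CCN2 (0.88), CDKN2B (0.80), TP53INP1 (0.67), SNAI2 (0.66), BTG2 (0.43) and ELF3 (0.40). With normexp the interaction was 0.04 for CCN2 and 0.10 for SNAI2, and both lost their calls; for CDKN2B it was 0.32. Of cell cycle and repair genes, E2F2 (0.67), TK1 (0.61), EXO1 (0.56), MCM10 (0.52), CDC45 (0.48), RAD54L (0.46), CENPM (0.41), RAD51 (0.37), RRM2 (0.34), CDCA3 (0.25) and AURKB (0.24) rose more in siFos cells, as did TFF1 (0.98) and FOS (0.39). PRSS23 (-1.73), STARD4 (-1.04), EGR3 (-0.96), PDZK1 (-0.72), SQLE (-0.53), FDFT1 (-0.49), PGR (-0.48), DHCR7 (-0.35) and NOP56 (-0.24) had a lower E2 effect in siFos cells. TMEM229A (3.6), ERG (2.61), GSTA5 (2.36), KCND2 (-2.15), HEY2 (-0.96) and ARHGAP36 (-0.57) differed as well, but were not well above background on every array, so that these sizes are uncertain; ARHGAP36 was at background on all 7 vehicle arrays.

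By list, the median interaction was 0.678 for estrogen-repressed genes, 0.277 for G1/S, 0.215 for homologous recombination, 0.188 for G2/M, 0.054 for p53 targets, -0.118 for the unfolded protein response, -0.145 for ribosome biogenesis, -0.193 for hypoxia, -0.232 for steroid receptors, -0.29 for estrogen-induced genes and -0.337 for cholesterol synthesis, each called by camera. With an estimated correlation the calls of the estrogen-repressed and cholesterol lists held.

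In 14 of 182 groups of 4 siFos arrays, 1 array stood far from the other 3 for a named gene by Dixon's test of the gap over the range, where chance gives about 1 in 20, or 9.1. In siFos E2 these were replicate 2 for EGR3 (-0.62), ARHGAP36 (-2.67), CDCA3 (1.53), RAD54L (1.85) and MYB (4.33), replicate 3 for IFI44L (-4.06), KLF2 (-0.93) and SHCBP1 (-0.56), replicate 1 for SERHL2 (0.40) and KCND2 (-6.99), and replicate 4 for PGR (-0.70). In siFos vehicle they were replicate 2 for MCM10 (-2.57) and SERHL2 (1.51) and replicate 4 for BMPER (-6.74). KCND2 and BMPER were at background in these groups.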

How the results depend on the processing

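The 2-fold and treat counts, the 2-fold counts under each alternative, and the alternatives for the overlap of the E2 effect in siControl cells with the siRNA effect in E2, were chosen only after the results were seen. The interaction count fell from 3212 to 1542 with median centring and to 1999 without the filter on dim probes; the cause was not tested. Changes of at least 2-fold numbered 1003 for E2 in siControl cells, 1371 for the siRNA in vehicle, 1457 for the siRNA in E2, 614 for E2 in siFos cells and 146 for the interaction; treat against 1.5-fold called 1394, 1724, 2087, 791 and 53; by construction both give fewer genes than the test against no change. Of 59 list calls by camera 16 held with an estimated correlation, 56 with quantile normalization (1 more was gained) and 58 with the replicate block, which ended the call of the unfolded protein list for E2 in siControl cells. The other counts of called genes, shared calls and list calls stayed within 1.5 times. The 2-fold counts in each direction moved more: with normexp they fell by over 1.5 times in every comparison, as the report gives. Without the filter the lower counts were 1163 (siRNA in vehicle), 753 (siRNA in E2) and 292 (E2 in siFos cells), and with the stricter filter 388, 306 and 93, with 41 higher and 19 lower for the interaction. Without each array in turn the counts ranged from 9627 to 10645 (E2 in siControl cells), 12280 to 13525 (siRNA in vehicle), 12434 to 13654 (siRNA in E2), 10307 to 11574 (E2 in siFos cells) and 2219 to 3183 (interaction), the FOS difference from -1.53 to -1.42 in vehicle and -1.12 to -1.03 in E2, and the shared calls from 7304 to 7695 (E2 in both arms), 9574 to 10220 (siRNA with and without E2) and 6637 to 7495 (opposite ways). List tests were not repeated without each array. Of 376 values of named genes 351 kept direction and call under every alternative in which they were recomputed. Of 8883 recomputed values 93 lost their call and 0 reversed. Apart from CAPS2 and TUBA3FP with the siRNA in E2, every value that lost its call was an interaction. IGFBP1 lost it in 18 of 22 alternatives, COL1A1 in 16 of 23 and KRT17 in 14 of 23. Most genes were named for their large called changes on these same arrays, which favours keeping the call. Leaving out an array outside a comparison does not move its fold changes. The stricter filter left 311 of the 376 values, and fits of only the compared groups leave out the interaction. The fit of every probe, which gave the probe ranges printed for some genes, is not in these counts. By over 1.5 times, 114 values moved with normexp, all to smaller changes (the report gives those it prints), 1 in the authors' table, 1 without siControl E2 replicate 1 and 2 without siControl E2 replicate 3. With median centring the median of all genes moved to -0.07 for the siRNA in vehicle and -0.09 in E2, and the share of called genes that were higher from 50.1% to 41% and from 51.2% to 38.7%. Residuals of arrays with the same replicate number correlated with a median r of 0.041 (19 pairs, 5 above 0.1), against -0.016 for 54 other pairs (0 above 0.1), and 12 of 14 arrays correlated best with an array of their own number, a hint that the numbers, which are also the slide columns, mark something shared. Since the labels state no pairing and not every pair exceeded 0.1, the arrays were not treated as paired; with the replicate block the counts were 10664, 13746, 13604, 11769 and 3125. A slide block was not run: it could not be fitted for the siRNA effects and changes nothing for the others. Signal over background limits the dim genes: 59.6% to 65.6% of probes were well above background per array.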

Other observations

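The gene list of motile cilia and all tests on it were chosen only after the results were seen, as was the comparison of siFos E2 with siControl vehicle cells. It was 1 of 3 groups looked at because single members stood out, and 4 of its members (DNAI7, DNAAF1, RSPH1 and DNAH7) drew attention to it and are left out of the counts. Gene symbols of the list were updated after a first look.

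Genes of the motile cilium, such as dynein arms, radial spokes and their assembly factors, were higher with the FOS siRNA. Of 66 listed genes 33 were measured; 23 rose and 4 fell with the siRNA in vehicle (median log2 0.80), and 23 rose and 2 fell in E2 (median 1.0). E2 lowered more of them than it raised, 15 against 5 in siControl cells (median -0.39) and 17 against 6 in siFos cells (median -0.27). The other 2 groups moved less. Of 16 measured antigen presentation genes 5 rose and 2 fell with the siRNA in vehicle, and 7 rose and 1 fell in E2 (medians 0.10 and 0.22). Of 8 apolipoprotein and cholesterol efflux genes 5 rose and 2 fell in vehicle, and 6 rose and 1 fell in E2 (medians 0.14 and 0.49).

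With E2, the siFos cells came back to about the siControl vehicle level of cell cycle genes: the G1/S list had a median difference from siControl vehicle of -1.09 without E2 and 0.06 with it, and the G2/M list of -1.0 and -0.07. The estrogen-induced genes of siFos E2 cells stood above that level by a median of 0.88, while interferon genes lay below it at -0.39. These comparisons between siFos and siControl cells also cross the slides.

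A slide difference that depends on signal level alone is argued against for the cilium genes. Their median with the siRNA in vehicle lay above 100% of 10000 random lists matched on mean signal (95% of these between -0.16 and 0.22). The random lists hold unrelated genes, whereas members of a list can vary together, and the list was chosen after these results were seen. The ranks against random lists here and below are therefore more extreme than a fair test would give. A candidate explanation is that cilium genes rise in starved or arrested cells in general: their median E2 effect in siControl cells had 0% of random lists below it. As the whole cause this was tested in siFos E2 cells, whose G1/S genes lay at 0.06. The cilium genes there still stood 0.59 above siControl vehicle cells (95% of random lists between -0.14 and 0.19). That cannot decide, since the comparison crosses the slides and other lists were not level (interferon -0.39, estrogen-induced 0.88). A difference between slides or cultures that is particular to these genes stays open, as does the knockdown itself.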
